A study of Trichoderma reesei QM6a with 24 samples.

How the data were processed

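Total RNA from mycelium of *Trichoderma reesei* was sequenced in 24 libraries, 3 for each of 8 groups: wild type QM6a and the deletion mutant QM6aΔ72004, whose gene was taken as locus tag TRIREDRAFT_72004, in constant light or constant darkness, with or without 5 mM L-methionine. Per the labels' protocols, cultures grew on cellulose in minimal medium at 28 °C. The growth protocol gives 96 h and the sample labels give 72 h, and nothing in the sources used here settles which holds. RNA was extracted with a plant mini kit and made into stranded libraries after depletion of ribosomal RNA, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

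The deposited table holds raw counts of read pairs per gene model, made by the authors with featureCounts 2.0.1 in its reverse stranded, paired mode, per the file headers. Alignment with HISAT2 2.2.1 is listed in the submitters' processing notes, and trimming is not given in the sources used here. The table lists 10879 gene models on 7 contigs and the mating-type locus, with a length for each model given by the authors in the deposited table. Nearly all of these lengths are multiples of 3, so they are taken as coding lengths. The build of the genome is not named in the count table, and coordinates are given as that table gives them. A second deposited file holds only a literature reference to the genome and no values. No normalization was applied to the counts before deposit, as far as the values show: all are whole numbers.

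Library totals ran from 13210988 to 21224989 counts. In a single library a floor of 3 counts corresponds to 0.141 to 0.227 CPM (counts scaled to a common library total). Folds against a group with no counts were computed against 3 counts over the whole group and are written as lower bounds. For a group with 1 to 3 counts the ratio is given with its 95% counting interval. These floors and intervals cover counting error only. No read was counted on 231 models.

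Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the package's own filter on low counts (minimum count 10) and the quasi-likelihood test in a one-factor model of the 8 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 9308 models. TMM factors ran from 0.877 to 1.114 and the common coefficient of biological variation was 0.133. Counts of models that also changed by at least 2-fold or 16-fold are given beside the calls. Log2 CPM used a prior count of 2, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values are means ± standard deviation (SD, n = 3 libraries). The comparisons were the effect of methionine in each genotype and lighting, the effect of the deletion in each lighting and medium, light against darkness in each genotype, and the interactions of methionine with genotype, methionine with lighting and deletion with lighting. Interaction values are differences of log2 fold changes.

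The labels number the samples of each group 1 to 3. Whether these numbers pair samples across groups was checked from the correlation of residuals between samples with the same number. In darkness the mean over 18 pairs was 0.05 (−0.17 to 0.47) and 3 pairs exceeded 0.1, all of them the wild type and mutant grown with methionine (0.37, 0.14 and 0.47). In light the mean was −0.06 (−0.43 to 0.2) and 2 of 18 exceeded 0.1. The numbers were therefore taken to pair samples only for the deletion effect in darkness with methionine, and a fit with the number as a block was run for all comparisons. The calls given come from the fit without the block. Within a lighting the block was shared by all groups, so that pairing alone was not modelled. With the block all 11 values of named genes in that comparison kept their call. Libraries from light and from darkness carry separate runs of library numbers, so lighting and library batch cannot be told apart.

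Gene names came from a reference table of QM6a (assembly GCF_000167675.1, v2.0), which shares 0 identifiers with the count table. Models were linked to locus tags by the lengths of their spans along the chromosome: a model was linked where its span was identical and at least 3 of its neighbours, counted over 6 on each side, also had identical spans in the same or fully reversed order. This linked 4005 of the 10879 models (36.8%), with a median of 5 identical neighbours, to a table of 9116 genes, 235 of which have a symbol of their own. Among the linked models 40 have such a symbol, and 36 of these were tested. The same procedure gave at most 0 links with 20 shuffled decoy tables, and 8730 of 8732 links were right when tested on simulated data. The simulated table was the count table itself, with a small part of the models dropped and of the spans altered. The real table differs more, since only 36.8% of models were linked, so this accuracy may not carry over to it. The number of neighbours was chosen after trying several settings, from the numbers of links and decoy links and not from expression. The names thus rest on gene order and span, and coordinates of the reference assembly were not used. Models without a symbol are named by identifier.

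Gene lists were fixed before the data were examined. Of these, 20 relied on product names, which the reference table does not give, and could not be run. Another 7 were given by locus tag and held 57 tags, 10 of which were linked and tested: 4 of 20 cellulases and accessory enzymes, 4 of 15 hemicellulases, 1 of 12 regulators of plant cell wall degradation and 1 of 5 genes of the sorbicillin cluster. The remaining lists had no linked member. The small share of members measured limits every statement about these lists. Lists of family 18 chitinases, G-protein and cAMP signalling genes, ribosomal proteins and vesicle traffic genes were built from symbols after seeing the data, as were the 7 contigs and the models within 100 kb of the outermost model of each contig. All 14 lists and regions were tested in each comparison with limma's camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and with an estimated one.

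The rule for naming genes was fixed before the data were examined: the deleted gene, the list members past the threshold with the largest changes, and per comparison up to 8 genes higher and 8 lower with an informative product name plus 2 identifiers in each direction. It required adjusted p under the threshold, a mean of at least 5 CPM in a group compared and, except for interactions, libraries of both groups that do not overlap. With no product names, models with a symbol of their own took their place. Other models are named where a count is small or where runs of neighbours, shares of all counts or absence of reads single them out, and these were chosen after their values were seen.

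The alternatives fixed before the data were examined were RLE size factors, no filter beyond 1 count, DESeq2 1.42.0 (Wald test), the replicate number as a block, a fit of only the libraries compared, and leaving out each library in turn. Added after seeing the data were a fit without the 20 most abundant models, libraries thinned to the lowest total, genotype interactions counted without the models beside TrC0447C, and runs of at least 5 tested models, consecutive once untested models are passed over, that changed the same way with an absolute log2 fold change of at least 2, set against 1000 shuffles of model order. Random draws used the seed 20240.

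The procedures were tested on simulated data. For the deletion effect in darkness, with 50 genes changed at each size, edgeR (9264 genes tested) recovered 6% of genes changed 1.2-fold, 50% at 1.5-fold, 94% at 2-fold and 96% at 4-fold, and 11 calls (8.21%) were of unchanged genes. DESeq2 (9308 genes) recovered 8, 56, 96 and 96%, with 20 such calls (13.5%). For the interaction of methionine with genotype in darkness edgeR recovered 0, 30, 80 and 92%, with 5 such calls (4.72%), and DESeq2 recovered 2, 36, 86 and 92%, with 20 (15.6%). With no gene changed, the deletion effect in light gave 1 call by edgeR and 2 by DESeq2. In the set test for the deletion effect in darkness, the raised set was called and 0 of 19 unchanged sets were. These sets were larger than the gene lists, held genes simulated without correlation and were tested on log2 CPM and not voom values. The result therefore does not carry over to the lists.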

Results

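Mycelium of *Trichoderma reesei* wild type QM6a and of the deletion mutant QM6aΔ72004 was profiled by RNA sequencing on cellulose, in constant darkness and in constant light, with and without 5 mM L-methionine. The title of the series names a G-protein coupled receptor in the response to methionine, so the comparisons ask how methionine changes expression, whether the change depends on the deleted gene, and how lighting enters. Each of the 8 groups holds 3 libraries, with total counts of 13210988 to 21224989 per library over 10879 gene models, 9308 of which were tested. Fold changes and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are in CPM, counts scaled to a common library total, given as means ± SD (n = 3). Gene names rest on links made by span and gene order to a reference table and cover 36 tested models.

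The model linked to locus tag TRIREDRAFT_72004 is TrE0303W (unitig_4_consensus 935227 to 936691, 4 exons, coding length 1215). It had 86 to 579 counts in each wild type library and 0 in each of the 12 mutant libraries, which makes it at least 1530-fold lower in the mutant and checks the genotype labels. In the wild type its level was 26.6 ± 2.73 CPM in darkness, 29.2 ± 1.27 in darkness with methionine, 6.08 ± 0.272 in light and 21 ± 3.09 in light with methionine (SD, n = 3). A second model, TrC0447C (linked to TRIREDRAFT_63200, unitig_2_consensus 1487256 to 1489332, 3 exons, coding length 1950), had 211 to 797 counts in each wild type library and likewise 0 in each mutant library, at least 1990-fold lower. Its wild type levels in the same order were 47.4 ± 3.19, 22.7 ± 1.53, 16.3 ± 1.2 and 23.6 ± 1.02 CPM. These were the 2 models with over 20 counts in every wild type library and none in any mutant library, and 0 models showed the reverse. Of the models around TrE0303W that were tested, TrE0300C, TrE0301C, TrE0302W and TrE0306C did not pass the edgeR threshold in any condition.

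**Figure D1:**
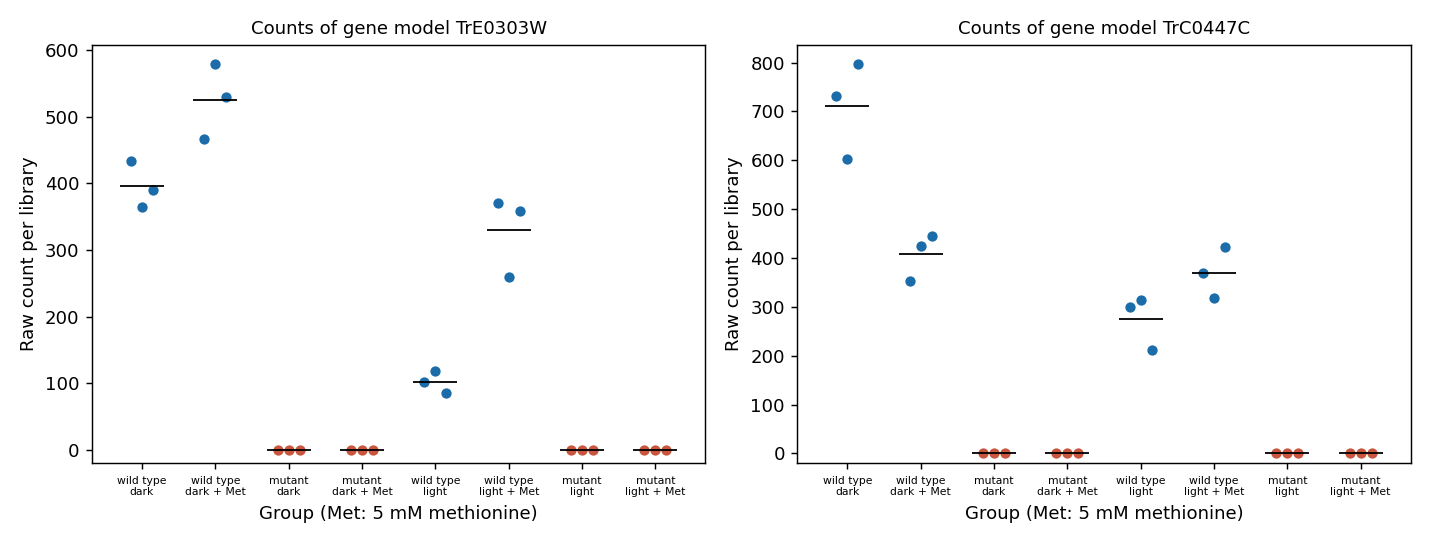
Raw counts per library of TrE0303W and TrC0447C in the 24 libraries, grouped by genotype, lighting and medium, with bars at the group means. Wild type libraries hold 86 to 579 counts of TrE0303W and 211 to 797 of TrC0447C, and all 12 mutant libraries hold 0 of both.

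Lighting and methionine, and not the genotype, separated the libraries. The first principal component carried 54.6% of the variance and set libraries with methionine apart from those without, and the second (29.8%) parted light from darkness, with a wider gap among the libraries without methionine than among those with it. The third carried 7.9% and the fourth 1.8%. Replicate 3 of the wild type in light lay apart from its group on the fourth component (−46.7). On the same component replicates 1 and 3 of the mutant in light (20.5 and 26.2) lay apart from replicate 2 (−3.7). The 10 most abundant models of each group took between 5.5% and 11.4% of all counts. TrE0391W, a short model of coding length 180, alone took 5.21 ± 1.85% of the counts of the wild type in light and 0.000438% in darkness.

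**Figure D2:**
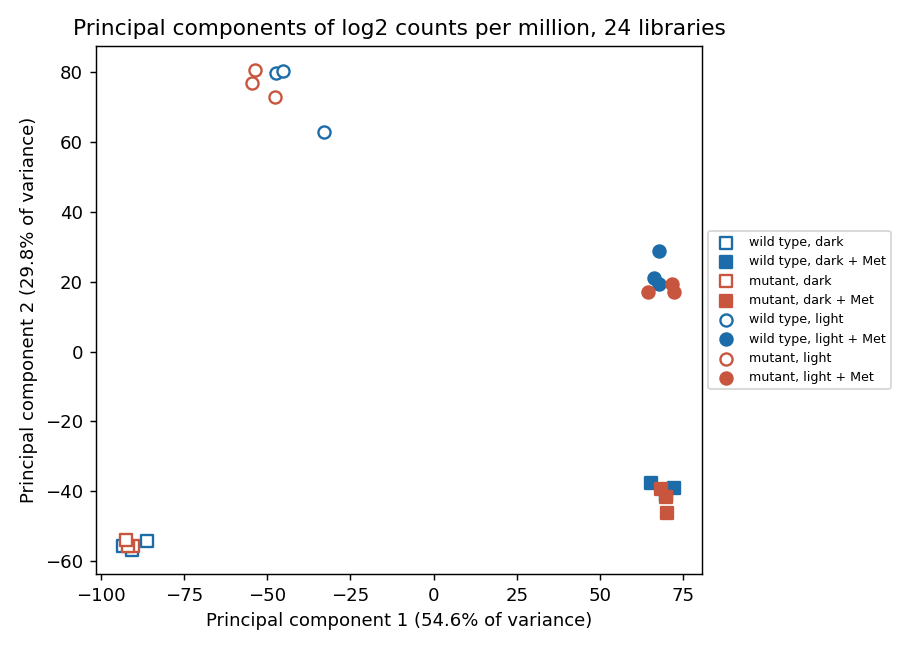
Scores of the 24 libraries on the first principal component (54.6% of the variance) and the second (29.8%), with a mark for each library by genotype, lighting and medium. Libraries with methionine lie to the right, and light lies above darkness both with and without it.

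Methionine in darkness lowered all 9 linked and tested members of the plant cell wall lists in the wild type. The beta-glucosidase gene cel1b fell from 831 ± 1.74 to 35.6 ± 2.55 CPM (SD, n = 3; log2 fold change −4.54, SE 0.09, edgeR adjusted p = 7.89e-19). The gene of the glucuronoyl esterase cip2, which carries a cellulose-binding module, fell from 105 ± 36.3 to 0.246 ± 0.104 CPM (−8.72, SE 0.5), and xyr1, which encodes the transcriptional activator of cellulase and xylanase genes, from 634 ± 21 to 171 ± 7.68 CPM (−1.89, SE 0.07). Among list members without a symbol, the cellulase list's TrG0019C (TRIREDRAFT_123992) fell from 1260 ± 171 to 22.7 ± 11.3 CPM and TrA2104C (TRIREDRAFT_76227) from 147 ± 6.21 to 45 ± 3.26. The hemicellulase list's TrG0018C (TRIREDRAFT_111849) fell from 940 ± 35.4 to 138 ± 45.2 CPM, with TrA2132C (−4.08), TrD0438C (−1.16) and TrC0659C (−1.09) in the same direction. All 9 measured members of the cell wall lists (of 47 locus tags) were lower, against 3439 of all 9308 tested models. The other listed tags were not linked to a model, so their response is unknown. The member of the sorbicillin cluster, TrE0663W (TRIREDRAFT_102497), fell from 217 ± 23.3 to 36.1 ± 1.56 CPM.

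Genes of G-protein signalling moved the other way. The gene of the regulator of G-protein signalling rgs1 rose from 48.7 ± 0.92 to 148 ± 13.9 CPM (1.60, SE 0.11, edgeR adjusted p = 2.62e-11). The gene of the catalytic subunit of protein kinase A, pkac2, rose from 26.5 ± 0.929 to 46.9 ± 3.25 CPM (0.83) and that of its regulatory subunit, pkar1, from 197 ± 1.62 to 327 ± 9.11 (0.73). The G-protein alpha subunit genes gna3 and gna2 rose from 76.8 ± 1.21 to 133 ± 9.19 CPM (0.79) and from 58.8 ± 4.2 to 88.4 ± 2.71 (0.59). Other genes that rose were mus38, a DNA repair gene (0.83), idh2, which encodes a subunit of isocitrate dehydrogenase (0.55), and taf19 (0.51). The ribosomal protein genes rps28 (−1.21), rps26 (−1.07), rpl15 (−0.94) and rps30 (−0.77) fell, as did psa7, which encodes a proteasome alpha subunit (−1.21, from 131 ± 10.9 to 56.8 ± 2.9 CPM). Of the chitinase genes, chi18-15 fell (−3.60, adjusted p = 0.000981 by edgeR; −4.39 without replicate 2 with methionine). Of the vesicle traffic genes, sso1, which encodes a SNARE of exocytosis, rose slightly (0.27) and sar1, which encodes the GTPase of COPII vesicles, fell (−0.48).

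Over all models, 7041 of 9308 (75.6%) passed the edgeR threshold in this comparison, 3602 higher and 3439 lower. At least 2-fold changes numbered 2144 higher and 1382 lower, and at least 16-fold changes 376 and 154. By fitted log2 fold change, which is no bound where a group has 0 counts, the largest rises included TrD1272C, from 0 to 16.3 ± 0.715 CPM (at least 243-fold), and TrG0922W, from 0 to 15.3 ± 5.4 CPM (at least 231-fold). The largest falls included TrD0146W, from 94.8 ± 46.1 to 0.0176 CPM (ratio 4970, counting interval 892 to 196000), and TrB0435C, from 817 ± 82 to 0.336 ± 0.249 CPM. As sets, camera called the cellulase list lower (adjusted p = 0.0168, and 0.133 with an estimated correlation) and the signalling genes higher (0.0333, and 0.235 with an estimated correlation). Hemicellulases and ribosomal proteins, each with 4 of 4 members lower, were not called as sets (both 0.0928), nor were chitinases or vesicle genes (both 0.838). Adjusted over the list alone, the counts of cellulases and hemicellulases were the same.

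In light the same addition of methionine gave a different picture for these genes. TrG0018C of the hemicellulase list rose from 8.83 ± 8.4 to 521 ± 305 CPM (5.92; 7.03 without replicate 3 of light) and TrG0019C of the cellulase list from 8.03 ± 2.45 to 34.2 ± 19.5 CPM (2.10). From levels that were already low, cel1b rose slightly, from 34.1 ± 3.57 to 43.9 ± 1.55 CPM (0.36, edgeR adjusted p = 0.000674), and xyr1 from 217 ± 4.97 to 258 ± 13 (0.25, adjusted p = 0.00476). Of the 9 measured cell wall members 4 were higher and 2 lower, with TrC0659C falling from 33.7 to 6.08 CPM (−2.47). The lower call of TrA2104C (−0.25) was lost without replicate 3 of light (−0.14) and without replicate 2 or 3 of light with methionine (−0.25 and −0.20). Adjusted over the list alone the cellulases kept 2 members higher and 1 lower and the hemicellulases 1 and 1. Camera called neither list (adjusted p = 0.969 for both), and for the hemicellulases the median (0.75) and mean (1.24) were positive while the direction of the test was down.

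Several other named genes responded to methionine in light. The family 18 chitinase gene chi18-9 fell from 228 ± 67 to 40.7 ± 2.96 CPM (−2.49), mata1, named for mating type, from 123 ± 22.7 to 39.8 ± 3.95 (−1.63), and blr2, which encodes a part of the blue light photoreceptor complex, from 169 ± 5.47 to 84.7 ± 0.976 (−0.99, SE 0.05, edgeR adjusted p = 2.52e-12). The ergosterol synthesis gene erg28 fell from 27.6 to 16 CPM (−0.78). pkac2 rose from 16.2 to 37.5 CPM (1.22), gna3 from 91.9 to 131 (0.51), sso1 from 61.6 to 107 (0.80) and snc1, which encodes another SNARE, by 0.39. The higher call of pkar1 (0.25) was lost without replicate 1 or 2 of the wild type in light (0.17 and 0.20), that of chi18-4 (0.49) without these (0.41 and 0.42) and without replicate 3 of light with methionine (0.41), and that of the exocytosis gene sec1 (0.22) without replicate 1 or 2 of light with methionine (0.20 and 0.18). The ribosomal protein genes rps26 (−1.31), rpl15 (−1.30), rps28 (−1.27) and rps30 (−0.53) fell and were called as a set (camera adjusted p = 0.0353, and 0.631 with an estimated correlation). Signalling, chitinase and vesicle genes were not called as sets (0.969 for signalling and vesicle genes).

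In light 6271 models (67.4%) passed the edgeR threshold, 3278 higher and 2993 lower, with 1713 and 964 at least 2-fold and 249 and 114 at least 16-fold. Without replicate 3 of the wild type in light, which lay apart, the number was 6229. TrC1371W (TRIREDRAFT_59267) rose from 0 to 124 ± 4.11 CPM (at least 2080-fold) and TrD1272C from 0 to 16.2 ± 1.7 (at least 273-fold). TrA0172W fell from 91.2 ± 117 to 0.0234 CPM and TrC0062W (TRIREDRAFT_112258) from 16.2 ± 20.5 to 0, starting levels carried by replicate 3 of light (23.5 and 4.4 CPM without it). Models near the contig ends leaned upwards, with 174 of 320 higher and 51 lower and a median of 0.92 (175 and 51 when adjusted over the list alone; camera adjusted p = 0.00244, and 0.631 with an estimated correlation). In darkness 150 of these were higher and 93 lower, which was not called (0.281).

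**Figure D3:**
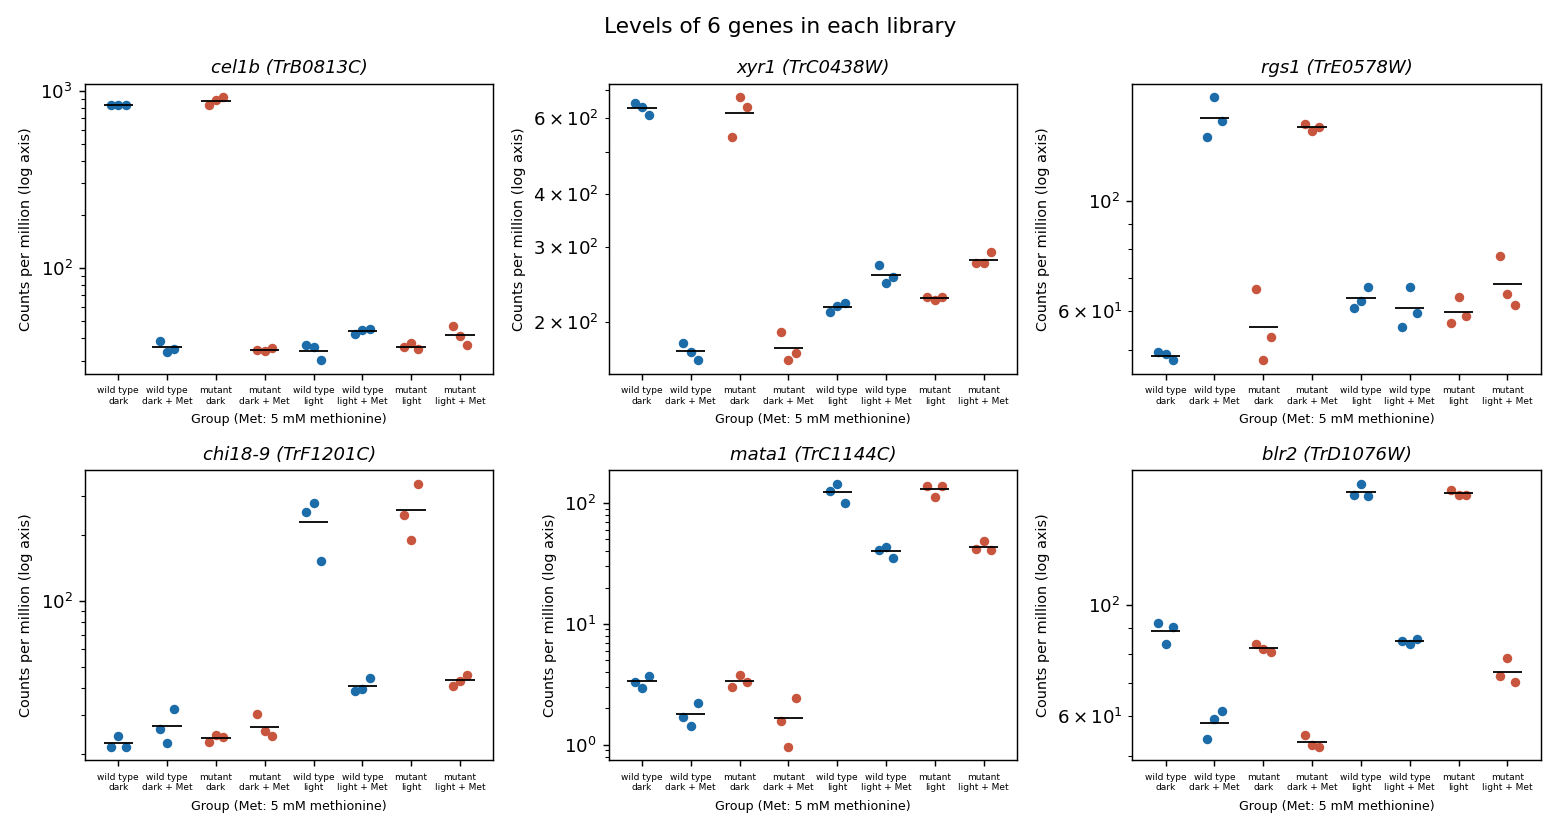
Levels in CPM (log axis) of cel1b, xyr1, rgs1, chi18-9, mata1 and blr2 in each library of the 8 groups, with a bar at each group mean. In the wild type without methionine, cel1b stands at 831 CPM in darkness and 34.1 in light, and wild type and mutant lie close together in each condition.

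Whether methionine acts differently in light and darkness was tested in the wild type as an interaction, here the response in light minus that in darkness. It was positive for cip2 (8.59, SE 1.62, edgeR adjusted p = 0.000182; 10.79 without replicate 3 of light and 7.91 without replicate 1 of light with methionine), cel1b (4.91, adjusted p = 7.42e-17), xyr1 (2.14, adjusted p = 2.56e-12) and psa7 (1.02), and negative for chi18-9 (−2.75), rgs1 (−1.67) and gna2 (−0.75). rgs1 in light went from 63.6 to 60.7 CPM with methionine (−0.07), which did not pass the threshold. Smaller differences were pkt1 (0.54), sso1 (0.53) and dhyS, the gene of deoxyhypusine synthase (0.43), and, on the negative side, idh2 and erg28 (both −0.50), pkar1 (−0.49) and blr2 (−0.39). The calls of snc1 (0.40) and rpl15 (−0.37) were less firm: that of snc1 was lost without replicate 3 of darkness with methionine (0.33) or replicate 2 of light with methionine (0.35), and that of rpl15 without replicates 1 or 3 of darkness, 1 of darkness with methionine, 1 or 2 of light, and 2 or 3 of light with methionine (between −0.36 and −0.30). Of the 9 cell wall members 8 were positive and 1, TrC0659C, was negative, with the call of TrA2132C lost without replicate 3 of light with methionine (4.68). In light without and with methionine cip2 stood at 0.32 ± 0.458 and 0.256 ± 0.175 CPM, and TrA2132C at 0.0236 and 0.0614. These levels are close to or under the floor of 3 counts in a library. Neither gene could fall much further there, so their positive differences restate the fall in darkness. Camera called the cellulases (4 of 4 positive, also when adjusted over the list alone; adjusted p = 0.000473, and 0.0232 with an estimated correlation), and not the hemicellulases (3 positive and 1 negative; 0.34).

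Across models 4618 differed between lighting conditions in their response to methionine, 2266 positive and 2352 negative, 980 and 1075 of them by at least 2-fold. Called in both lighting conditions in the same direction were 4497 models, 2338 higher and 2159 lower, and 2004 of these still differed in size, 1474 being larger in darkness and 530 larger in light. Another 641 went in opposite directions, 272 higher in darkness and lower in light and 369 the reverse. Some of the called differences rest on groups with few or no counts, so their fitted size is no bound. TrA0865C (TRIREDRAFT_110666) stood at 115 ± 5.06 CPM in darkness and at most 0.0722 in the other wild type groups, and its call was lost without replicate 3 of light with methionine (fitted difference 10.46). TrD1022C (TRIREDRAFT_105763) stood at 334 ± 100 CPM in light, at most 7.93 with methionine, and 0 in darkness. Because libraries from light and darkness carry separate runs of library numbers, lighting and library batch cannot be told apart.

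A small part of the models that answered methionine stood side by side among the tested models, with untested models between them passed over, a feature chosen after the values were seen. In darkness 13 runs of at least 5 neighbours changed at least 4-fold in the same direction, 12 up and 1 down, with 73 of the 1171 higher and 541 lower models of that size, against a mean of 0.26 runs and at most 3 in 1000 shuffles of model order. By length the runs do not stand out, since the longest held 7 models and shuffles reached 9 (8 in light). In light there were 7 such runs (6 up, 1 down, 41 of 835 higher and 380 lower models), against a mean of 0.05 and at most 1. The 7 models from TrC1369C to TrC1376C (unitig_2_consensus 4650388 to 4663180, 12.8 kb) rose together from 14.7 ± 0.967 to 1640 ± 16.1 CPM in darkness and from 31 ± 1.99 to 1590 ± 62.3 in light, and in the mutant 7 of 7 rose in darkness and the 6 models called in light, TrC1369C to TrC1375W, in light. The 6 models from TrA2098C to TrA2103W rose from 24.9 to 3140 ± 926 CPM in darkness. The 5 models from TrC1100C to TrC1105C fell from 692 to 51.7 CPM.

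The mutant kept these responses. In darkness cel1b fell from 880 ± 48.5 to 34.5 ± 0.719 CPM (−4.67), xyr1 from 619 ± 68.2 to 174 ± 14 (−1.83) and cip2 from 160 ± 15.7 to 0.106 ± 0.184, while rgs1 rose from 55.7 ± 9.59 to 141 ± 2.35 (1.34). In light chi18-9 fell from 260 ± 77.3 to 43.2 ± 2.6 CPM (−2.59), mata1 from 129 ± 15.6 to 43.7 ± 4.25 (−1.57) and blr2 from 167 ± 2.07 to 73.5 ± 4.18 (−1.19), and pkac2 rose from 17.1 to 35.2 (1.04). TrG0018C rose in light from 3.96 to 505 ± 625 CPM (6.99), a level carried by replicate 3 with methionine (145 CPM and 5.18 without it). All 9 measured cell wall members fell in darkness, and in light 5 rose and 1 fell. Among those 5, the call of cel1b in light (0.21) was lost when only the groups compared were fitted and without replicate 1 or 3 of light (0.21 and 0.19) or replicate 1 of light with methionine (0.12).

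In the mutant 7192 models (77.3%) passed the edgeR threshold in darkness, 3683 higher and 3509 lower, with 2227 and 1311 at least 2-fold. In light 6672 did (71.7%), 3477 higher and 3195 lower, with 1977 and 993 at least 2-fold. In darkness TrA0432C rose from 0 to 29.5 ± 4.01 CPM (at least 456-fold) and TrG1034W (TRIREDRAFT_72605) from 0 to 13.5 ± 2.08 (at least 214-fold), while TrD0146W fell from 153 ± 22.8 to 0.0182 CPM (ratio 9130, counting interval 1640 to 361000) and TrB0435C from 901 ± 42.8 to 0.167. In light TrF1120W (TRIREDRAFT_67692) rose from 0 to 58.4 ± 6.96 CPM (at least 1020-fold) and TrC1371W from 0.0204 to 151 ± 11.8 (ratio 7950, counting interval 1430 to 314000). TrC1533C fell from 65.1 ± 30 to 0.0481 CPM (ratio 1310, counting interval 449 to 6370) and TrF0330C (TRIREDRAFT_103179) from 24.8 ± 6.83 to 0.0351 (ratio 770, counting interval 213 to 6360). As sets in darkness the cellulases were called lower (camera adjusted p = 0.0213, and 0.168 with an estimated correlation). In light the ribosomal proteins were called lower (0.0498, and 0.56 with an estimated correlation) and the contig ends higher (189 of 320 higher and 49 lower, median 1.21; 0.000224, and 0.56 with an estimated correlation).

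Log2 fold changes of wild type and mutant, which share no library, correlated across models at Pearson 0.966 and Spearman 0.968 in darkness and at 0.924 and 0.917 in light (across genes, which are not independent replicates). Of 6530 models called in both genotypes in darkness 6523 went the same way, and of 5626 in light 5624 did. By contrast the wild type's responses in darkness and in light correlated at 0.604 and 0.606.

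Whether methionine acts differently in the 2 genotypes was tested directly. In darkness TrE1139W fell from 30 to 1.88 CPM in the wild type and from 21.9 to 4.32 in the mutant (difference of log2 fold changes 1.65, SE 0.19, edgeR adjusted p = 0.000387), and its call held in all alternatives. TrB0737W went from 7.09 to 7.16 CPM in the wild type and from 8.6 to 23.4 in the mutant (1.43, SE 0.26, adjusted p = 0.0453), TrC1474W from 156 to 91.4 and from 132 to 132 (0.77), and TrC0448W differed by 0.69. With the replicate block the calls of TrB0737W and TrC0448W in darkness were lost. In light TrC0973C (TRIREDRAFT_103579) went from 7.25 to 7.33 CPM and from 3.79 to 9.08 (1.24, SE 0.19, adjusted p = 0.0155), TrC0448W differed by 0.69 and TrC0446C by 0.64. The replicate block cost 1 of these calls in light. TrC0446C and TrC0448W are the direct neighbours of the missing TrC0447C.

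These 4 models in darkness and 3 in light, all with the larger or less negative response in the mutant, were the whole of the edgeR calls, with 695 and 1248 models at an unadjusted p under 0.05 and 31 and 54 calls by DESeq2. In darkness the count was 22 without replicate 2 of the wild type, 2 without replicate 3 of the wild type or of the mutant with methionine, and 1 without any of the other 9 libraries. In light it was 0 by edgeR without replicate 1 or 2 of the wild type with methionine or replicate 1 of the mutant without (1115, 1238 and 905 at an unadjusted p under 0.05), 31 without replicate 2 of the mutant, 8 and 1 without replicates 2 and 1 of the mutant with methionine, and 6, 5 and 1 without replicates 1, 2 and 3 of the wild type. No list of genes was called. The contig ends in light were (median 0.24; camera adjusted p = 0.00396, and 0.595 with an estimated correlation).

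The deletion itself moved few models in any single condition. In darkness without methionine TrE0663W of the sorbicillin cluster list was lower in the mutant, 217 ± 23.3 against 130 ± 16 CPM (−0.74, edgeR adjusted p = 0.000616), and the 5 neighbours from TrE0659C to TrE0663W together held 1360 ± 202 CPM in the wild type and 587 ± 111 in the mutant. That sum was not tested, and the run was picked by its change between light and darkness. The run beside it, TrE0665C to TrE0671C, went the other way, with 4410 ± 289 CPM in the wild type and 5310 ± 404 in the mutant. TrD0368W and TrD0790W were higher, 75.4 ± 2.96 against 97.1 ± 8.26 CPM (0.37) and 135 ± 2.61 against 169 ± 13.4 (0.32). In light TrF0330C was higher in the mutant, 9.05 ± 3.64 against 24.8 ± 6.83 CPM (1.45, adjusted p = 0.0331), as was TrG0053C, 98.9 ± 6.36 against 154 ± 15.9 (0.64). With only the compared libraries fitted, TrE0663W (−0.74), TrD0368W, TrD0790W, TrF0330C and TrG0053C were not called. Of the named calls in darkness 2 were lost with the replicate block and 2 without the filter on low counts. In light 1 was lost with the replicate block. Of the cell wall genes, cel1b differed by 0.08 in darkness and 0.07 in light (edgeR adjusted p = 0.697 for both), and xyr1 by −0.04 and 0.07 (0.881 and 0.675). cip2 stood at 105 ± 36.3 CPM in the wild type and 160 ± 15.7 in the mutant in darkness (0.60, edgeR adjusted p = 0.334) and TrG0018C at 8.83 ± 8.4 and 3.96 CPM in light (−1.12, adjusted p = 0.536), differences that did not pass the threshold. Without replicate 3 of the wild type in light TrG0018C stood at 3.98 CPM there, close to the mutant.

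The edgeR test called 19 models in darkness (3 higher, 16 lower; 1311 at an unadjusted p under 0.05; 151 by DESeq2) and 14 in light (5 higher, 9 lower; 1346; 260). In darkness the count was 5, 58 and 6 without wild type replicates 1, 2 and 3, and 49, 50 and 8 without those of the mutant. In light it was 263, 274 and 5 without wild type replicates 1, 2 and 3, and 5, 312 and 7 without those of the mutant. Among the higher models, TrD0368W was no longer called without replicates 1 or 3 of the wild type or 1 or 2 of the mutant (0.30 to 0.37), TrD0790W without any wild type replicate or mutant replicate 1 or 3 (0.26 to 0.36), and TrF0330C (1.16 to 1.45) and TrG0053C (0.55 to 0.69) without wild type replicate 3 or mutant replicate 1 or 3.

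With methionine most called models were higher in the mutant. In darkness TrB0737W stood at 7.16 ± 1.02 CPM in the wild type and 23.4 ± 1.94 in the mutant (1.71, edgeR adjusted p = 1.38e-05), and TrA1852C (TRIREDRAFT_58475) at 1.8 ± 0.648 and 5.91 ± 2.62 (1.72), a call lost without replicate 2 of the wild type (1.60) and with only the compared libraries fitted (1.71). In light TrC1580C stood at 24.6 ± 3.48 and 65.8 ± 6.27 CPM (1.42, adjusted p = 0.00156) and TrA0404W (TRIREDRAFT_106287) at 2.09 and 5.09 (1.29, a call lost without wild type replicates 1 or 3, at 1.25 and 1.14, and with only the compared libraries, at 1.29). Both neighbours of TrC0447C were higher in the mutant with methionine: TrC0446C at 90.1 and 135 CPM in darkness (0.59, adjusted p = 5.22e-05) and 90.1 and 156 in light (0.79, adjusted p = 7.38e-07), and TrC0448W at 61.6 and 90.1 (0.55) and at 131 and 240 (0.87). With only the compared libraries fitted, the calls in darkness were lost (TrC0446C 0.58, TrC0448W 0.54). Without methionine neither passed the threshold (TrC0446C 0.20 and 0.15, TrC0448W −0.14 and 0.18 in darkness and light). cel1b differed by −0.04 and −0.07 and xyr1 by 0.02 and 0.12, without passing the threshold.

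The edgeR test called 50 models in darkness with methionine (45 higher, 5 lower; 770 at an unadjusted p under 0.05; 115 by DESeq2) and 32 in light with methionine (28 higher, 4 lower; 855; 101). In darkness the count was 31 and 16 without wild type replicates 1 and 2, and 18 without mutant replicate 3. In light it was 19, 15 and 19 without wild type replicates 1, 2 and 3, and 83 and 20 without mutant replicates 1 and 3. Over the 4 conditions 93 models were called in 1, 7 in 2, 0 in 3 and 2, the missing models, in all 4. The conditions with methionine shared 6 higher models. If the calls were independent 0.14 would be shared. Both comparisons use 1 spread per gene estimated over all 24 libraries, so the calls are not independent and 0.14 does not measure chance. The shared models were TrC0446C, TrC0448W, TrB0493C (1.31 in darkness and 0.89 in light), TrC0159C (0.69 and 1.27), TrD1304C (0.97 and 0.72) and TrF0416W (1.42 and 0.89). The other 4 shared calls were lost in more fits. In light this was so with the replicate block (TrB0493C, TrD1304C and TrF0416W), with only the compared libraries (all 4), without wild type replicates 1 (TrD1304C, 0.66, and TrF0416W, 0.89), 2 (TrB0493C, 0.84, TrD1304C, 0.67, and TrF0416W, 0.82) or 3 (TrB0493C, 0.82) and mutant replicates 1 (TrD1304C, 0.65) or 3 (TrB0493C, 0.74, TrD1304C, 0.72, and TrF0416W, 0.89), and in darkness with only the compared libraries (TrC0159C and TrD1304C) and, for TrC0159C, without wild type replicates 1 or 2 (0.59 and 0.68) or mutant replicates 2 or 3 (0.70 and 0.61). The contig ends were called in light with methionine (6 higher, 8 when adjusted over the list alone, median 0.15; camera adjusted p = 1.63e-06, and 0.339 with an estimated correlation).

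Light without methionine also lowered the linked cell wall genes. In the wild type cel1b stood at 831 ± 1.74 CPM in darkness and 34.1 ± 3.57 in light (−4.60), cip2 at 105 and 0.32 (0.0554 without replicate 3 of light) and xyr1 at 634 ± 21 and 217 ± 4.97 (−1.55). TrG0018C of the hemicellulase list stood at 940 ± 35.4 and 8.83 ± 8.4 CPM (3.98 without replicate 3 of light), lower than the 138 ± 45.2 reached with methionine in darkness, and all 9 measured members of the cell wall lists were lower. mata1 rose from 3.35 ± 0.384 to 123 ± 22.7 CPM (5.19), chi18-9 from 22.3 ± 1.52 to 228 ± 67 (3.36) and blr2 from 88.7 ± 4.46 to 169 ± 5.47 (0.93). gna2 rose from 58.8 to 93.4 CPM (0.67), idh2 from 290 to 446 (0.62) and rgs1 from 48.7 to 63.6 (0.39), whereas psa7 (−1.01), pkac2 (−0.71) and chi18-6 (−0.53) fell. TrE0391W went from 4.67 ± 3.27 to 55500 ± 19200 CPM and TrD1022C from 0 to 334 ± 100 (at least 5120-fold). TrA0865C fell from 115 ± 5.06 CPM to 0 (at least 1920-fold) and TrE0671C from 2200 ± 158 to 0.337 ± 0.451 (−12.8; −14.58 without replicate 3 of light and −12.19 without replicate 1 of light). The 5 models from TrE0665C to TrE0671C (unitig_4_consensus 2206789 to 2222382) fell together from 4410 ± 289 to 1.11 ± 1.49 CPM, 1 of 11 runs of neighbours, all lower in light, with 63 models (mean 0.03 and at most 2 in 1000 shuffles).

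In the wild type 6029 models (64.8%) passed the edgeR threshold between light and darkness, 3029 higher and 3000 lower in light, with 1157 and 1288 at least 2-fold. Without replicate 3 of light the number was 5771. Camera called the cellulases lower (adjusted p = 0.00275, and 0.0595 with an estimated correlation), with 4 of 4 members lower, as were 4 of 4 hemicellulases, which were not called as a set (0.0653). Lighting and library batch cannot be told apart.

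In the mutant cel1b went from 880 to 36 CPM (−4.61), xyr1 from 619 to 228 (−1.44), mata1 from 3.37 to 129 (5.26), chi18-9 from 23.6 to 260 (3.46) and blr2 from 81.9 to 167 (1.03), and sso1 fell by 1.25. TrE0391W rose from 5.48 ± 3.2 to 63200 ± 11100 CPM and TrD1022C from 0.0433 to 320 ± 35 (ratio 7520, counting interval 2080 to 62100), while TrE0671C fell from 2640 ± 62.8 to 0.179 CPM and TrE0669C from 816 ± 133 to 0.0506 (ratio 14300, counting interval 4890 to 69300). In all 5806 models (62.4%) passed the edgeR threshold, 2962 higher and 2844 lower. Camera called the cellulases lower (adjusted p = 0.0017, and 0.045 with an estimated correlation), the hemicellulases lower (0.0253, and 0.125 with an estimated correlation) and the contig ends lower (82 higher and 148 lower of 320; 0.0327, and 0.617 with an estimated correlation). The effects of light in wild type and mutant correlated across genes at Pearson 0.92 and Spearman 0.885, and 4933 of 4943 models called in both went the same way.

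Whether the deletion acts differently in light and in darkness was tested without methionine. TrE0011C stood at 24.1 CPM in darkness and 0.473 in light in the wild type, and at 20.1 and 2.29 in the mutant (2.51, edgeR adjusted p = 0.00879), a call that held in all alternatives, and its near neighbour TrE0013C (TRIREDRAFT_71010) at 7.36 and 0.14 and at 5.94 and 1.01 (3.12, SE 0.51, adjusted p = 0.0121). Both belong to the 7 neighbours from TrE0011C to TrE0017C, which together held 1.28 CPM in the wild type in light and 7.01 in the mutant, against 65.7 in the wild type in darkness. TrG0241W, TrE0663W and, with a negative difference (−0.70, adjusted p = 0.0105), TrG0916W complete the 5 calls by edgeR (4 positive, 1 negative; 1238 at an unadjusted p under 0.05; 81 by DESeq2). The count was 21 without wild type replicate 2 in darkness, 29 without mutant replicate 1 in darkness, 2 and 3 without wild type replicates 1 and 2 in light, and 2 and 46 without mutant replicates 1 and 2 in light. The call of TrE0013C was lost without any of the wild type replicates in light (2.95 to 3.30) or without mutant replicate 1 in light (2.96), that of TrG0916W without replicate 1 of either genotype in light (both −0.67), and that of TrG0241W without 7 of the 12 libraries and with the replicate block. With only the compared libraries fitted, TrE0663W (0.89) and TrG0241W (1.37) were not called. The 0.14 CPM of TrE0013C in the wild type in light lies at the floor of 3 counts in a library. Here too lighting and library batch cannot be told apart.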

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

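The counts over other splits of the samples were planned before the results were seen, and the other tests given here, on the models beside TrC0447C, on distances to the missing models and on splits that mix both media, were chosen only after. Most of what follows was picked out because an interaction test found the effect to differ between groups. Groups of 3 libraries are too small to be searched for outliers.

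Methionine acted differently in the genotypes for 4 models in darkness, among them TrE1139W (1.65), TrB0737W (1.43) and TrC0448W (0.69), and for 3 in light, TrC0973C (1.24), TrC0448W (0.69) and TrC0446C (0.64). The splits do not settle whether chance can be excluded in darkness: 8 of 100 gave as many calls (highest of the others 11, real value 4), but 5 of these keep or exchange all 3 libraries of a medium and so carry the genotype difference, and of 83 made up of the real split and those that mix both media 3 gave as many (highest of the others 6). In light chance is not excluded, with 21 of 100 splits, and 11 of 82 counted in the same way, giving as many calls (highest of the others 760, real value 3). A count of 760 is many times the real one and points to a structure of the samples in light, since that split exchanged replicates 1 and 3 without methionine and replicate 1 with methionine between the genotypes. A candidate explanation for the 3 calls beside TrC0447C is the missing locus itself, acting on its neighbours, which cannot be told apart from an effect of the deleted receptor gene because both models are missing in the same libraries. The 4 other called models lie more than 5 models away from both missing models, on another contig (TrB0737W) or 1027 (TrC1474W), 836 (TrE1139W) and 526 (TrC0973C) models off, so closeness to a missing locus does not explain these. An effect of either missing model from a distance may remain there, and the 2 cannot be told apart.

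In light single libraries decide the calls of the genotype interaction: the count falls from 3 to 0 by edgeR without replicate 1 or 2 of the wild type with methionine or replicate 1 of the mutant (1115, 1238 and 905 models at an unadjusted p under 0.05, and 54 calls by DESeq2 with all libraries), is 1 without replicate 3 of the wild type or replicate 1 of the mutant with methionine, and is 6, 5, 8 and 31 without replicates 1 and 2 of the wild type, replicate 2 of the mutant with methionine and replicate 2 of the mutant. In darkness it is 2 with the replicate block, TrB0737W and TrC0448W being lost, 22 without replicate 2 of the wild type, 2 without replicate 3 of either genotype with methionine and 1 without any of the other 9 libraries, and TrE1139W is called each time.

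Methionine acted differently in light and darkness for 4618 models of the wild type. Other splits decide nothing here: 2 of 100 gave as many calls (highest of the others 5848), but they exchange libraries between light and darkness, where 6029 models differ. Where both media are mixed, the groups take on a large spread and call few models whatever the interaction. Where 1 medium is kept whole, its difference between the lighting conditions remains, and such splits called many models, for example 4504 and 3939. The split with 5848 exchanged all 6 methionine libraries and so carries the difference between the lighting conditions itself. Named genes with a positive difference were TrA0865C (12.44), TrE0669C (11.94), cip2 (8.59), cel1b (4.91), xyr1 (2.14), psa7 (1.02), pkt1 (0.54), sso1 (0.53), dhyS (0.43) and snc1 (0.40). Negative differences were found for TrF0388W (−12.79), TrD1022C (−12.65), chi18-9 (−2.75), rgs1 (−1.67), gna2 (−0.75), idh2 and erg28 (both −0.50), pkar1 (−0.49), blr2 (−0.39) and rpl15 (−0.37). For cip2 both groups in light lie close to the floor, so its value restates the fall in darkness. The values of TrA0865C, TrE0669C, TrF0388W and TrD1022C are fitted over groups with few or no counts, depend on the prior count and are no bounds. Single libraries move them and cip2: TrA0865C to 13.64 and TrD1022C to −10.41 without replicate 3 of darkness with methionine, TrE0669C to 11.34, 11.30 and 16.66 without replicates 1, 2 and 3 of light, TrF0388W to −11.73 without replicate 3 of light, and cip2 to 10.79 without replicate 3 of light and 7.91 without replicate 1 of light with methionine. Of all these, the calls of TrA0865C (10.46 without replicate 3 of light with methionine), snc1 (0.33 without replicate 3 of darkness with methionine, 0.35 without replicate 2 of light with methionine) and rpl15 (−0.36 to −0.30 without 7 single libraries) did not hold throughout. Lighting and library batch cannot be told apart.

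The deletion acted differently in light and darkness for 5 models, TrE0013C (3.12), TrE0011C (2.51), TrE0663W, TrG0241W and TrG0916W (−0.70). Of 100 splits, the real one included, 2 gave as many calls, with 13 as the highest of the others. These splits exchange the genotypes within each lighting, so they stand for no difference between the genotypes at all. Against that alone they argue, for the number of calls and not for any single model. They cannot decide against a deletion effect that is equal in light and darkness. The number also rests on single libraries, and lighting and library batch cannot be told apart. The count is 2 without replicate 1 of the wild type or of the mutant in light, 3 without wild type replicate 2 in light, and 21, 29 and 46 without wild type replicate 2 in darkness, mutant replicate 1 in darkness and mutant replicate 2 in light. TrE0011C is called in each of these fits, and TrE0663W is not with only the compared libraries fitted (0.89).

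Reads on the mating-type locus, which no comparison uses, were picked out because their number exceeds 0: mat1-1-1 had 13 reads in all, in 9 of 12 libraries from light, at most 3 in a library, and 0 in the libraries from darkness. mat1-1-2 and mat1-1-3 had 0. No library exceeds the floor of 3 counts, and libraries from light carry their own run of library numbers. Whether the reads stem from this locus was not tested, and no expression in light is read from them.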

How the results depend on the processing

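Not counting the models beside TrC0447C, thinning the libraries and leaving out the 20 most abundant models were chosen after seeing the data. Counts of calls in the deletion and genotype comparisons depended on the processing, and those of the other comparisons stayed within 1.5 times, although single named genes lost their call there too. With only the compared libraries in the fit, edgeR called 3 models for the deletion in darkness, 2 in light, 12 in darkness with methionine and 7 in light with methionine, and 0 for the genotype interaction in light (902 at an unadjusted p under 0.05, and 54 calls by DESeq2), against 19, 14, 50, 32 and 3. That alternative fits fewer libraries, while the causes of the other shifts were not tested. DESeq2 called 151, 260, 115 and 101 models for the deletion, including 19, 14, 49 and 32 of those called by edgeR, 31 and 54 for the genotype interactions (main values 4 and 3) and 81 for the deletion by lighting (main value 5). Without a filter the deletion in darkness had 11 calls. With the replicate block it had 6, light with methionine 20 and the genotype interaction in darkness 2. Not counting the models beside TrC0447C, the genotype interaction in light kept 1. Leaving out 1 library gave 5 to 58 calls for the deletion in darkness, 5 to 312 in light, 16 to 56 in darkness with methionine, 15 to 83 in light with methionine, 1 to 22 and 0 to 31 for the genotype interactions in darkness and light, and 2 to 46 for the deletion by lighting, with the libraries named beside each result. The direction of the deletion calls in darkness changed too, from 3 higher and 16 lower to 88 and 63 with DESeq2. The correlation of the methionine responses in darkness was 0.988 over models with at least 10 CPM and 0.956 to 0.963 without 1 library (main value 0.966), and in light 0.897 to 0.937. With an estimated correlation 2 of 14 calls of lists and regions remained in number. The methionine responses, light against darkness and methionine by lighting stayed within 1.5 times their main counts under all alternatives, with 6740 to 6858 and 5843 to 6229 calls for methionine in the wild type in darkness and light without 1 library. Of 253 values of named genes 207 kept their call under all alternatives, 46 lost it under at least 1, and 0 changed sign. At this depth a 1.2-fold effect of the deletion in darkness was rarely recovered in simulated data (6%).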

Other observations

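The tests weighed here on the missing model and on the breadth of the methionine response were chosen only after the results were seen, and the counts over other splits were planned before. A few models took large shares of all reads in some conditions and far smaller ones in others. In the wild type TrC1130C, of coding length 261, held 2 ± 0.28% of the counts in darkness and 0.529% in light, and 0.0228% and 0.0203% with methionine. TrG0022C and TrC1166C held 1.28 ± 0.0906% and 1.16 ± 0.0207% in darkness and at most 0.00447% in the other 3 conditions. TrD1010C went the other way, with 0.0302% in darkness and 0.215% in light against 0.632% and 1.17% with methionine. TrF0363W reached 0.877% in darkness with methionine and 0.197% without, and 0.0427% in light and 0.00935% in light with methionine. TrC1552C held 1.36 ± 0.965% in light with methionine. The longest of the abundant models, TrB1256C, of coding length 29481, held 0.524% in light and 0.0318% with methionine.

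Further runs of neighbouring models moved together. The 7 models from TrF0111W to TrF0117C rose with methionine in darkness from 7.48 to 135 CPM together, and the 7 from TrD0030C to TrD0036W rose with methionine in light from 120 to 5000 ± 2990. The 5 models from TrC1429C to TrC1433W fell with methionine in light, from 298 to 38.7 CPM. Light lowered the 6 models from TrD1309W to TrD1315W by a median log2 fold change of −5.04.

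TrC0447C lacks reads in the same 12 mutant libraries as TrE0303W. Genotype labels exchanged between libraries are argued against by the targeted model alone: 0 libraries had reads on TrE0303W against their label. Reads shared between the models are argued against as well: the ratio of TrC0447C to TrE0303W was 1.8 ± 0.215, 0.777 ± 0.0585, 2.69 ± 0.245 and 1.14 ± 0.125 in the wild type in darkness, darkness with methionine, light and light with methionine, so the highest and lowest means differ 3.46-fold, while replicates of a group differ by at most 1.24-fold. What stays open is a difference between strains: the strain in which the receptor gene was deleted may already have lacked TrC0447C, or lost it along the way, and since all 12 mutant libraries carry both losses this cannot be told apart from a consequence of the deletion without a second mutant. Effects of the deletion given here could therefore belong to either model.

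Methionine changed most tested models, which could come from technical features of the libraries. In the wild type in darkness 7028 models were called without the 20 most abundant models, against 7041 with them. This cannot decide on a few abundant genes as the cause. The 20 models hold 9% of all counts, and TMM already limits the weight of extreme models in the scaling. Library size is argued against by 6923 calls after thinning all libraries to the lowest total, and a wrong scaling of the libraries as the whole cause by the spread of the changes: 3628 models lay at least 2-fold from no change, and no single shift of all log2 fold changes left fewer than 3590 at that distance. No biological explanation of the breadth was tested.

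For comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Most tested models differ with methionine and with lighting, so groups that mix these take on a large spread and call few models. For those comparisons the other splits decide nothing. The real split was the only 1 of the 10 to reach its count for methionine in the wild type in darkness (7041, highest of the others 0) and light (6271, 3), methionine in the mutant in darkness (7192, 0) and light (6672, 0), light against darkness in the wild type (6029, 5) and the mutant (5806, 0), and the deletion in darkness (19, 7). For the deletion in light 2 splits reached 14, the highest of the others giving 145 by setting replicates 1 and 3 of the wild type with replicate 2 of the mutant against the rest. That is about 10 times the real count and points to a structure of the samples that the genotype does not follow. In light with methionine 3 splits reached 32, the highest of the others giving 91 by setting replicate 1 of the wild type with replicates 2 and 3 of the mutant. In darkness with methionine, where the replicate numbers pair the samples, 2 splits reached 50. The split with 70 set replicate 1 of the wild type with replicates 1 and 2 of the mutant and thus parted only 1 of the 3 pairs, whereas the splits that part all 3 pairs gave 0 calls by edgeR apart from the real one (770 models at an unadjusted p under 0.05 in the real comparison, and 115 calls by DESeq2).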
